A study of Homo sapiens with 124 samples.

How the data were processed

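Single-cell DamID maps the parts of the genome that touch a protein of interest in one cell at a time. The bacterial methyltransferase Dam is fused to the protein, here LaminB1, a main protein of the nuclear lamina that lines the inside of the nuclear envelope. Adenines in GATC motifs near the lamina become methylated in the living cell, the enzyme DpnI cuts the methylated motifs, and the fragments are amplified and sequenced. The samples were single cells of KBM7, a near-haploid human line from a chronic myeloid leukaemia. All 124 samples are labelled as haploid cells of clone 14 that carry Dam-LaminB1. Per the labels' protocols, Dam was induced with 0.5 nM Shield1 for 15 h, sorting took the smallest 2% of cells carrying both markers of the Fucci cell cycle reporter, and the amplification had 21 extension steps. Shield1 is a small molecule that stabilises fusion proteins carrying a destabilising domain.

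The authors deposited 1 table of the whole series, with a ratio of observed to expected reads in consecutive bins of 100 kb for each cell. The unit was read from the table's name and from the values, since the labels do not describe the expected part. Per the submitters' processing notes, the tools cutadapt and Bowtie2 2.1.0 and the genome build hg19 were used. What each tool was used for, the further steps and the settings are not given in the sources used here. The table holds 30376 bins and columns for 118 of the 124 cells, and the samples numbered 33, 34, 44, 86, 95 and 120 were not analysed here. A DamID profile of unfused Dam, which measures how accessible each region is, was not used here, so accessibility was not separated from lamina contact beyond what the expected part of the ratio corrects. Sequences named 9:22 and 22:9 stand in place of chromosomes 9 and 22, and the line is known to carry the Philadelphia translocation between them. Positions on 9:22 and 22:9 count along those sequences. No value was present in any cell in 3792 bins, which include all 1464 bins of chromosome 8 and the 289 bins of chromosome 15 from 61000001 to 89900000. KBM7 is known to carry an extra copy of chromosome 8 and of a part of chromosome 15, and whether that is the reason is not given in the sources used here.

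Bins were usable if they had a number in every cell and a value above 0 in at least 1 cell. This left 26426 bins, or 2642.6 Mb, after 158 bins at 0 in every cell were removed. Whole reads were recovered from the ratios, because each value was a whole number of reads multiplied by a step of the bin and a step of the cell. To a tolerance of 0.02 reads, 100% of the 1697710 values above 0 came out whole. Recovered reads are the reads behind the usable bins, with no molecular identifiers, and it is not known whether duplicates were removed. They numbered 28372 to 385661 per cell, with a median of 135782. In the median bin a value of 1 stood for 1.17 reads in the shallowest cell, 5.63 reads in the median cell and 15.9 reads in the deepest cell. In 14 cells it stood for under 3 reads, so that single reads decide contacts there.

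A bin was in contact in a cell if its value was at least 1. The contact share of a cell is the percentage of usable bins in contact, and the contact frequency of a bin is the percentage of the 118 cells in which it was in contact. A contact run is a series of consecutive usable bins in contact. Frequencies were compared with 100 references in which the contacts of each cell were shifted circularly along each chromosome, and runs with 100 references in which the contact bins of each cell were permuted within each chromosome. The signal of a bin is the median value over the cells in contact, for bins in contact in at least 5 cells, and its 100 references, added after the data were seen, permuted the values over the contact bins of each cell. Coordination is the Pearson correlation over cells of the contacts of bin pairs, after the contact share of the cell was removed by regression, for bins at 20 to under 80%. Its references permuted each bin over cells, or whole chromosomes between cells. Chromosome ends are the outermost usable bins, and the centromere gap is the longest stretch without usable bins, on chromosomes whose usable bins start within 5 Mb of the sequence start. Relations between measures of cells were tested two-sided with 100000 permutations and Benjamini-Hochberg adjustment over 10 relations. The number of reads was added to these measures after the data were seen. Exact Clopper-Pearson intervals at a confidence level of 95% cover the counting of cells only.

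The labels name no cultures, so the cells were treated as a single group, without knowing whether they came from 1 culture or several. The labels give no groups to compare, so no test between groups of the study was made. The sets of cells by sample number are not such groups, and the closing tests of background compare them. SDs measure the spread between cells. Comparisons lie within the genome and are descriptive. The regions named are the 10 longest stretches of bins at 80% or more, the 5 longest at 5% or less and the 5 longest at 40 to under 60%. The chromosomes named are the 3 highest, the 3 lowest and chromosome 8, and the cells named are the highest and lowest of each measure. These rules, the measures and comparisons above unless said to be added, and most alternatives were fixed before the data were examined. The split by sample number, the relations with recovered reads and the tests of missing chromosomes, of background and of thinned reads were chosen after the data were seen. Other chromosomes, regions and cells named were chosen after their values were seen.

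The recovery of reads and the measures were tested on simulated data with 26426 bins and 118 cells. Recovered reads equalled the simulated ones in 99.9999% of values. Recovered and simulated contact frequencies had a correlation of 0.991 across bins, with a mean absolute difference of 1.70 percentage points. Simulated bins had a single signal level in contact and a single far lower level elsewhere, with counting error of reads only. Observed signal was not so cleanly separated, so these values do not measure the accuracy of the observed frequencies. With contacts drawn independently per bin, without simulated reads, the mean correlation at 0.2 to 0.5 Mb was 0.000546, which checks the calculation only. With simulated reads and contacts shared in blocks of neighbouring bins, the mean correlation was 0.803 at 0.2 to 0.5 Mb and -0.00159 over 5 to 10 Mb. Alternatives changed the contact value, the cells, the bins, the frequency classes, the bridging of runs and the removal of the contact share. Those chosen after seeing the data thinned each cell to 50000 reads, used the cells numbered 1 to 94 or 96 to 124 alone, left out cells that lack most reads of a chromosome, or took signal and frequency from different cells. Planned comparisons with gene lists, gene density and GC content were left out, because the gene table at hand is on GRCh38.p14 and not on hg19, and the sequence of hg19 was not used here. The computation used Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1.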

Results

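Contacts with the nuclear lamina were mapped in single haploid KBM7 cells, and 118 cells were analysed as 1 group from a single clone. Recovered reads per cell had a mean of 137812 ± 61934.5 (SD, n = 118), from 28372 in cell 43 to 385661 in cell 100. The contact share was 33.0% ± 5.47 of the usable bins per cell (SD, n = 118), from 18.3% in cell 89 to 42.3% in cell 97. Bins without any read made up 45.6% ± 14.4 of the usable bins, from 7.82% in cell 100 to 77.2% in cell 89. All SDs over cells measure the spread between cells, and the labels do not say whether the cells came from 1 culture.

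The single-cell maps address which parts of the genome touch the lamina in nearly every cell, in some cells and in none. A set of 3981 bins, or 398.1 Mb and 15.1% of the usable genome, was in contact in at least 80% of the cells. These bins held 39.2% of all contacts. No contact was seen in any cell in 5889 bins, or 22.3% of the usable genome, and 28.8% of bins were in contact in under 20% of the cells. The remaining 8946 bins, or 33.9%, were at intermediate frequencies of 20 to under 80% and held 55.8% of all contacts. After circular shifts of the contacts in each cell, no bin reached 80% in any of the 100 references, 0.283% of bins had no contact and 90.6% were intermediate. The SD of the frequency over bins was 34.0 percentage points, against 10.2 after shifts. No bin was in contact in all cells. The highest frequency was 97.5% (115 of 118 cells, exact 95% interval 92.7 to 99.5%), reached by 3 bins, among them chromosome 2 from 226300001 to 226400000. A bin with 0 of 118 cells in contact allows a frequency of up to 2.54% by the limit of 3 counts, or 3.08% as the exact upper bound, counting error of cells only. With each cell thinned to 50000 reads, an alternative chosen after seeing the data that left out 9 shallower cells, bins at 80% or more fell to 9.69% and bins at 0% to 14.2%. The classes also depend on the contact value, since bins at 80% or more made up 26.8% at a contact value of 0.5 and 0.0946% at a contact value of 2, and bins at 0% made up 4.95 and 35.9%. A limit of 90% in place of 80% left 1.94% of bins.

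**Figure D1:**
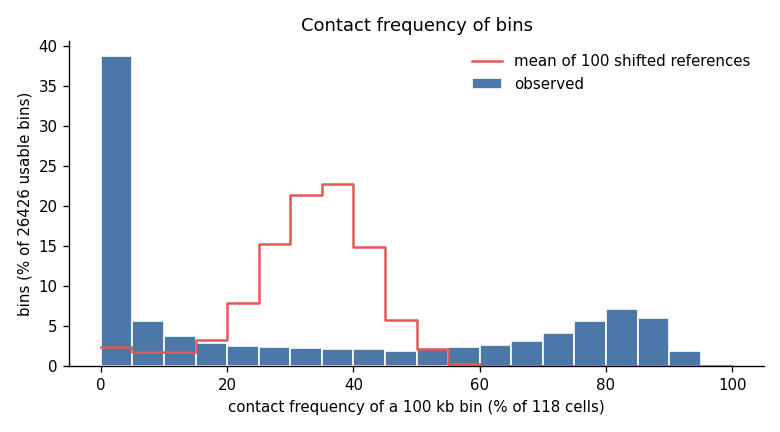
Histogram of the contact frequency of the usable bins (x axis, percentage of the 118 cells in contact, in steps of 5) with the percentage of bins on the y axis; bars are observed and the line is the mean of 100 references with contacts shifted along each chromosome. Observed bins pile up at both sides, with 38.8% of bins under 5% and 7.11% at 80 to under 85%, whereas shifted contacts peak at 35 to under 40% with 22.8% of bins.

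The longest stretches of frequent contact lay on chromosomes 3 and 7. On chromosome 3 the stretch from 173300001 to 176500000, 3.2 Mb on the long arm, had a mean frequency of 90.3%, and each cell had 90.3% ± 14.7 of it in contact (SD, n = 118). No cell lacked contact there, and 114 of 118 cells had more than 50% of the stretch in contact. Chromosome 7 from 144600001 to 147800000, also 3.2 Mb on the long arm, had a mean frequency of 88.6% ± 20.5, and 1 cell had no contact there. On the short arm of chromosome 3, the 2.6 Mb from 20400001 to 23000000 reached 86.9% ± 21.2. The 2.4 Mb from 8500001 to 10900000 on the short arm of chromosome 7 reached 90.0% ± 14.3 and held bins at up to 97.5%. Chromosome 3 from 165000001 to 167400000 followed with 88.1% ± 16.4, and chromosome 4 from 181000001 to 183100000 with 87.2% ± 20.9. The other stretches among the 10 longest were chromosome 5 from 165100001 to 167100000 at 86.7% ± 23.9, sequence 9:22 from 104800001 to 106800000 at 85.5% ± 24.7, chromosome 4 from 91300001 to 93300000 at 85.3% ± 19.3, and chromosome 11 from 96400001 to 98300000 at 89.3% ± 17.5. In all, 1085 stretches were at 80% or more, with a median length of 0.2 Mb, and 82 of them spanned at least 1 Mb.

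The longest stretches with rare contact were longer than the longest frequent ones, whereas the median lengths were close, with 0.3 Mb for stretches at 5% or less. Chromosome 19, known as the most gene-dense human chromosome, held the longest on its short arm, 19.7 Mb from 200001 to 19900000 with a mean frequency of 0.194%, and 95 of 118 cells had no contact anywhere in it. A second stretch of chromosome 19, the 13.5 Mb from 43700001 to 57200000, had 0.377%. On the short arm of chromosome 1 the 12.7 Mb from 17200001 to 29900000 had 0.153%, and the 12.2 Mb from 35100001 to 47300000 had 0.264%. On the short arm of chromosome 3 the 11 Mb from 42400001 to 53400000 had 0.277%. Of 1221 stretches at 5% or less, 265 spanned at least 1 Mb. The contacts in these stretches came mostly from cells numbered 96 to 124, whose signal in rarely contacted bins was higher. On the short arm of chromosome 19 the mean was 0.544% in these cells and 0.0846% in cells 1 to 94, and in the stretches of chromosome 1 it was 0.591 against 0.0175% and 0.761 against 0.109%.

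Stretches at 40 to under 60% were short, and only 6 of 1349 spanned at least 1 Mb. Within the longest ones, the share in contact varied widely between cells. On chromosome 1 from 57100001 to 58800000, 49.2% ± 40.1 of the 1.7 Mb was in contact per cell (SD, n = 118), with no contact in 29 cells, over 50% of the stretch in contact in 61 cells and a smaller part in 28 cells. On chromosome 13 from 85200001 to 86400000 the share was 51.6% ± 38.0, with no contact in 18 cells, over 50% in 58 and a smaller part in 42. On chromosome 7 from 28400001 to 29600000 it was 50.2% ± 39.9, with no contact in 27 cells, over 50% in 55 and a smaller part in 36. On chromosome 15 from 53100001 to 54200000 it was 49.4% ± 41.6, with no contact in 33 cells, over 50% in 61 and a smaller part in 24. On sequence 9:22 from 87000001 to 88000000 it was 50.8% ± 39.4, with no contact in 22 cells, over 50% in 57 and a smaller part in 39. Cells numbered 96 to 124 had higher means than cells 1 to 94 in 4 of these 5 stretches, for example 72.9 against 43.1% on chromosome 7, and a lower mean on chromosome 13, 42.9 against 54.4%.

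**Figure D2:**
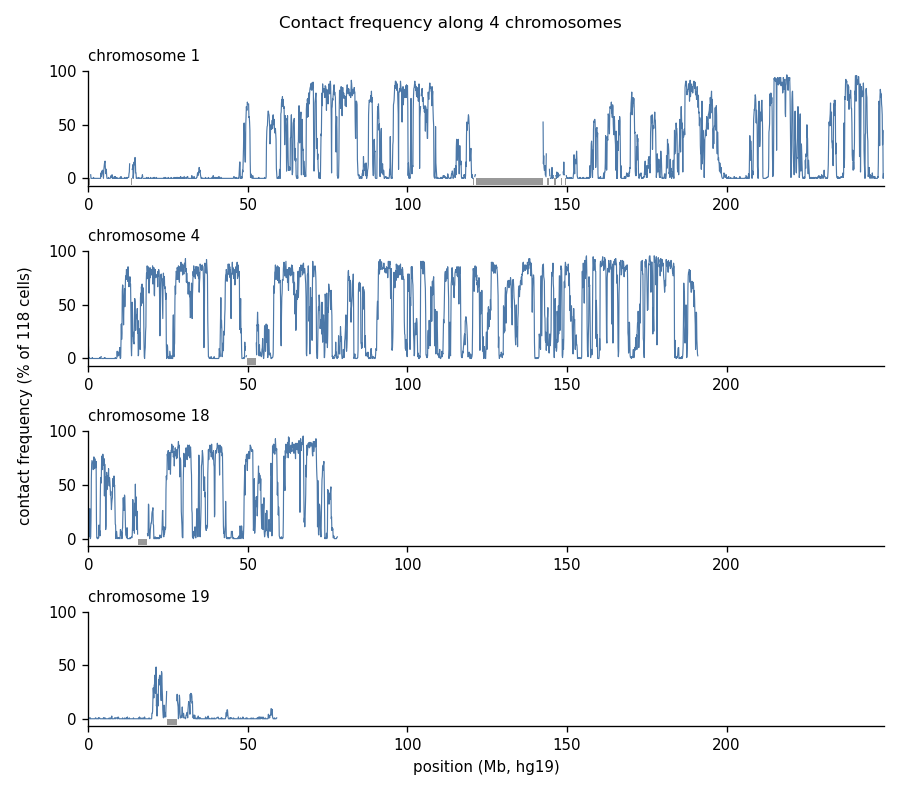
Contact frequency of 100 kb bins (y axis, percentage of the 118 cells) along chromosomes 1, 4, 18 and 19 (x axis, position in Mb on hg19), with bins without usable values in grey. On chromosome 4, 24.3% of bins are at 80% or more and 10.2% at 0, with the others in between, the short arm of chromosome 1 holds long stretches near 0, and chromosome 19 stays near 0 outside the surroundings of its centromere gap.

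Chromosomes differed in how much of their length touched the lamina. Chromosome 4 was highest, with 46.2% ± 8.67 of its bins in contact per cell (SD, n = 118), followed by chromosome X with 44.0% ± 9.35 and chromosome 18, known to be gene-poor, with 41.4% ± 9.93. The derivative sequence 22:9 was lowest with 0.715% ± 1.05, followed by chromosome 19 with 2.95% ± 2.80 and chromosome 17 with 9.45% ± 5.26. By sample number, 22:9 had 0.536% in cells 1 to 94 and 1.29% in cells 96 to 124, chromosome 19 had 2.67 and 3.88%, and chromosome 17 had 8.35 and 13.0%. Chromosome 4 exceeded chromosome 19 in 118 of 118 cells, by 43.3 percentage points ± 8.88. Chromosomes 18 and 19, which are of similar size, differed by 38.4 points ± 10.2, again in 118 of 118 cells, and chromosome 18 exceeded chromosome 17 in 117 of 118 cells. No bin of chromosome 19 or of 22:9 reached 80%, whereas 26.7% of the bins of chromosome X and 24.3% of those of chromosome 4 did. The order of the 3 highest was less clear, as chromosome 4 exceeded X by 2.26 points ± 8.12, in 78 of 118 cells, and X exceeded 18 by 2.61 points ± 9.74, in 71 of 118 cells. Chromosome 8 had no values and was not analysed here.

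**Figure D3:**
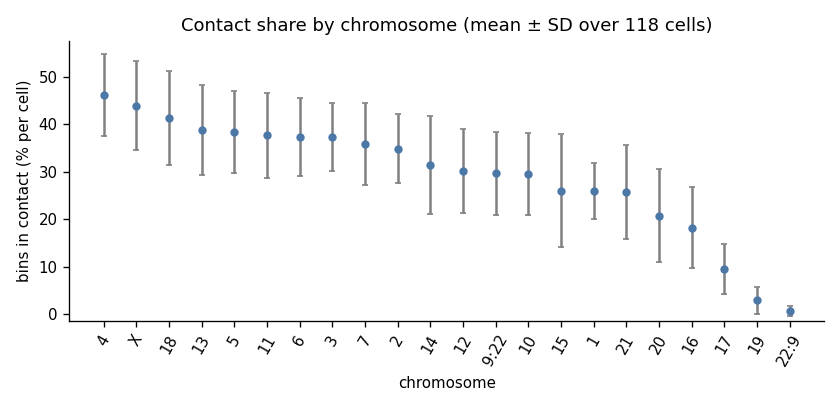
Percentage of the bins of each chromosome in contact per cell (y axis), as mean (points) and SD over 118 cells (bars), with chromosomes on the x axis in falling order. The means range from 46.2% on chromosome 4 to 0.715% on 22:9.

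Contact also varied with position along the chromosome. Bins within 2 Mb of a chromosome end were in contact in 10.8% ± 3.47 of cases per cell (SD, n = 118), bins at 2 to under 10 Mb in 25.1% ± 6.19 and bins farther away in 35.1% ± 5.57. Ends were lower than bins at 10 Mb or more on 16 of 17 chromosomes with usable bins on both arms. Chromosomes 12 and 16 had 0.127 and 0.106% at their ends, against 33.3 and 20.2% farther away, whereas chromosome 3, the exception, had 40.5% at its ends and 36.1% farther away. Within 2 Mb of the centromere gap no common direction was seen across chromosomes. Bins within 2 Mb of the gap had 28.9% ± 6.76, bins at 2 to under 10 Mb 24.8% ± 4.84 and bins at 10 Mb or more 34.4% ± 5.82. Values within 2 Mb were higher than at 10 Mb or more on 8 of 17 chromosomes. Chromosomes 3 and 11 had 61.6 and 61.0% near the gap, and chromosomes 2 and 4 had 9.51 and 12.0%.

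Within a cell, contacts formed long runs. The mean run over all cells was 0.497 Mb, against 0.160 Mb when contact bins were permuted within each chromosome. Runs of at least 1 Mb held 54.3% of contact bins (0.382% after permutation), and single-bin runs held 7.60% (40.1% after permutation). The number of runs was 1753 ± 277 per cell (SD, n = 118), from 1368 in cell 61 to 2664 in cell 98. The mean run of a cell ranged from 0.280 Mb in cell 49 to 0.706 Mb in cell 85. Part of this spread went with the sample number. Cells 1 to 94 had a median of 1603 runs and a mean run of 0.543 Mb, and cells 96 to 124 had 2068.5 runs and 0.460 Mb. The longest run spanned 10.4 Mb of the short arm of chromosome 5, from 20600001 to 31000000 in cell 38, and 16 cells had their longest run within 17.2 to 31.4 Mb of that arm. The long arm of chromosome 12 between 80.2 and 89.3 Mb held the longest run of 12 cells. Bins in longer runs were also contacted more often in the other cells. Their frequency in the other cells was 47.1% ± 7.37 for single-bin runs and 75.6% ± 3.23 for runs of at least 2 Mb (SD over 118 cells). Run length depends on depth and on gaps of single bins. The mean run per cell of 0.506 Mb ± 0.102 became 0.379 Mb with 50000 reads per cell and 0.905 Mb when gaps of 1 bin were bridged, and the share of contact bins in runs of at least 1 Mb became 36.8 and 76.4%. At a contact value of 2 that share was 19.8%.

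The signal of bins in contact was compared with their frequency, and both are read from the same values, so that a general rise of a bin's values raises both. The median ratio in contact was 1.45 for bins under 20%, 1.99 for bins at 20 to under 80% and 2.50 for bins at 80% or more. Across 16538 bins, which are not independent replicates, Spearman's rho of signal and frequency was 0.828. It was 0.768 and 0.775 when signal and frequency came from different cells, odd- or even-numbered. With both from the odd- or both from the even-numbered cells it was 0.769 and 0.775. The lower values thus go with the smaller number of cells. In 100 references with the values permuted over the contact bins of each cell it was 0.209 to 0.238. Within single cells, rho of the values of contact bins with their frequency averaged 0.289 ± 0.0952 (SD, n = 118) and was above 0 in 118 of 118 cells.

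Single cells shared more of their contact profile than shifted contacts did. The correlation of a cell with the mean of all other cells had a median of 0.741, against 0.186 after shifts, and ranged from 0.501 in cell 36 to 0.842 in cell 38. For 6903 pairs of cells, the Jaccard index, which is the share of bins in contact in either cell that were in contact in both, had a median of 0.519, quartiles of 0.452 and 0.579, and a range of 0.248 to 0.709. After shifts its median was 0.217.

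Regions at intermediate frequency tended to be in contact in the same cells when they lay on the same chromosome. The mean correlation over cells of neighbouring bins was 0.473. It was 0.170 at distances of 2.1 to 5 Mb, 0.0583 at 20.1 to 50 Mb and 0.0198 at over 50 Mb, each above the range of 100 permuted references. Between chromosomes it was -0.00328, below the permuted range of -0.00136 to 0.00167. It was smaller in size for bins at 40 to under 60%, -0.000537, and at a contact value of 0.5, -8.47e-05. No references were made for these 2 settings. The contact shares of chromosome arms were compared after the contact share of the cell was removed in the same way. Both arms of a chromosome then had a mean correlation of 0.330 ± 0.145 (SD over 17 chromosomes). It was above 0 on 17 of 17, from 0.0506 on chromosome 1 to 0.581 on chromosome 20. Arms of different chromosomes had a mean correlation of -0.0265 ± 0.110 (SD over 544 pairs). Removing the contact share of the cell sets the level between chromosomes, for bins and for arms. For bin pairs it was 0.0484 without that removal.

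**Figure D4:**
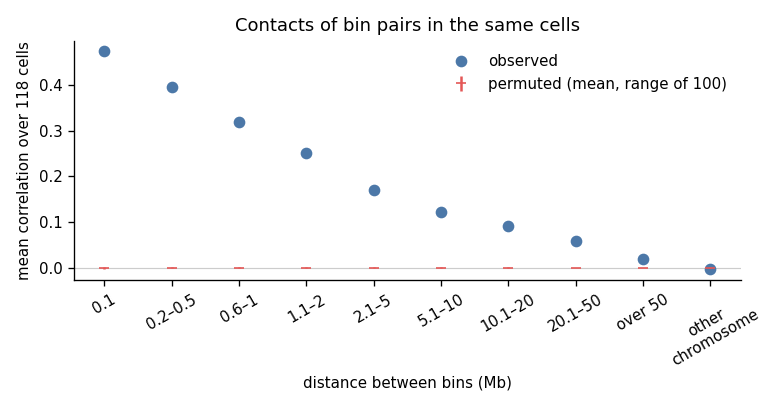
Mean correlation over 118 cells (y axis) of the contacts of bin pairs at 20 to under 80%, by distance on the chromosome in Mb and for pairs on other chromosomes (x axis), with the mean and range of 100 permuted references. The observed mean falls from 0.473 at 0.1 Mb to 0.0198 at over 50 Mb and is -0.00328 between chromosomes.

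Measures of the cells were related to one another. Cells with more recovered reads had a larger contact share, with Pearson's r = 0.822 and Spearman's rho = 0.872 (n = 118, permutation p = 1e-05 for each, the smallest that 100000 permutations can give, adjusted p = 1.11e-05 and 1.25e-05). Without the 2 cells farthest from the median contact share r was 0.815, and it was 0.871 in cells 1 to 94 and 0.755 in cells 96 to 124. At a contact value of at least 2, r was 0.135. Cells with longer mean runs were more similar to the other cells, with r = 0.865 and rho = 0.858 (permutation p = 1e-05 for each, adjusted p = 1.11e-05 and 1.25e-05), and r was 0.859 without 2 cells, 0.867 in cells 1 to 94 and 0.781 in cells 96 to 124. Both of these measures also rose with recovered reads, the mean run with r = 0.697 and rho = 0.729 and the similarity with r = 0.554 and rho = 0.598 (permutation p = 1e-05 for each), and in cells 1 to 94 their r with reads was 0.876 and 0.755. These measures all come from the same values of a cell, and a bin without reads cannot be in contact. Some relations were therefore partly built in. All 10 relations had an adjusted p of at most 0.00782, and these p-values treat single cells as units. The weakest was between the share of bins without reads and the similarity to the other cells, with r = -0.340 and rho = -0.245. It was stronger within the number sets, with r = -0.774 in cells 1 to 94 and -0.410 in cells 96 to 124.

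**Figure D5:**
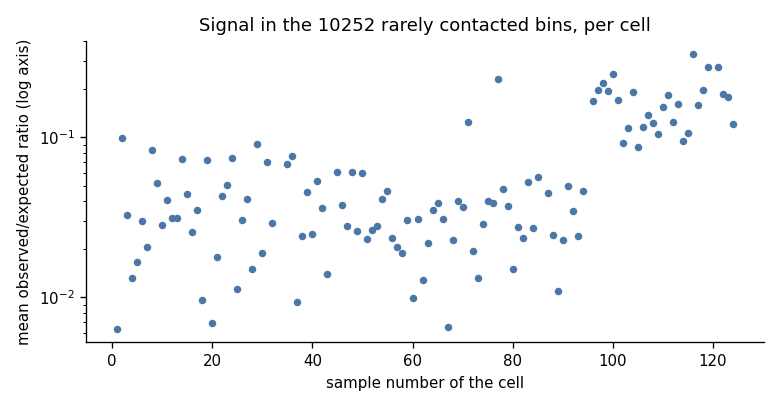
Mean ratio in the 10252 bins contacted in at most 5% of cells (y axis, log scale) for each cell, by sample number (x axis). Cells 96 to 124 lie at 0.0873 to 0.330, and 4 of the 90 cells numbered 1 to 94 lie above 0.0873.

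Cells differed in the signal of rarely contacted bins by their sample number, a split seen only in the data. In the 10252 bins contacted in at most 5% of cells, the mean ratio had a median of 0.0309 over the 90 cells numbered 1 to 94 and of 0.164 over the 28 cells numbered 96 to 124. The extremes were 0.00639 in cell 1 and 0.330 in cell 116. The frequencies of bins in both sets of cells had a correlation of 0.936 across bins, and bins at 80% or more made up 16.1 and 16.2%. Less frequent bins differed more between the sets. However, these classes and the 10252 bins were chosen on all 118 cells, 90 of them numbered 1 to 94. That choice favours low values in cells 1 to 94 for the less frequent classes. Mean frequencies in cells 1 to 94 and 96 to 124 were 1.10 and 4.15% for bins above 0 to 5%, 8.20 and 19.9% for bins above 5 to under 20%, and 25.9 and 42.1% for bins at 20 to under 40%. In bins at 80% or more the mean ratio was 2.66 in cells 1 to 94 and 2.02 in cells 96 to 124. The mean ratio of a cell over its bins lay between 0.871 and 0.995, so more signal in rare bins leaves less for the others. The median share of bins without any read was 48.4% in cells 1 to 94 and 28.7% in cells 96 to 124. The median correlation of a cell with the mean of all other cells was 0.753 and 0.691.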

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

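Of 201 values of 15 results under 22 alternatives, 140 stayed within the criterion of their result. It was 1 SD between cells for measures of cells, chromosomes and ends, 1 SD over 20 random draws of 59 of the 118 cells for correlations between bins, rho across bins and the share in runs of at least 1 Mb, 1.5 times for shares of bins, and the side of the test for the relation with reads. Another 59 moved, 1 lost its call and 1 changed sign. Some of the 140 could not move, such as chromosomes 4, 18 and 19 on autosomes only, or run lengths and correlations between bins with the bins at 0 kept. The SD between cells is also a wide limit for a mean over 118 cells. At a contact value of 2, chromosome 19 had 1.12% against 2.95% and still counted as within it. The alternatives with 50000 reads per cell, by sample number, without 8 cells that lack most reads of a chromosome, or with signal and frequency from different cells were chosen after seeing the data. Contacts at 0.5 or more gave a mean contact share of 41.6%, 4.95% of bins at 0%, 26.8% at 80% or more, a mean run of 0.638 Mb, a correlation between chromosomes of -8.47e-05, 56.6% on chromosome 4, 5.94% on chromosome 19, 15.1% at chromosome ends and a rho of signal and frequency of 0.888. Contacts at 2 or more gave 18.8%, 35.9%, 0.0946% and 0.276 Mb for the first 4 of these, a similarity of 0.591, correlations of 0.127 at 2.1 to 5 Mb and -0.00209 between chromosomes, 26.4% on chromosome 4, 5.91% at ends, rho 0.580, and r = 0.135 between contact share and reads, which no longer passed the test.

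With 50000 reads, 14.2% of bins were at 0% and 9.69% at 80% or more, the mean run was 0.379 Mb, both correlations were 0.124 and -0.00172, and rho was 0.744. The high class held 24.9% of bins from 70% and 1.94% from 90%. Runs became longer by construction with means over 5 bins, 2.11 Mb, and with bridged gaps, 0.905 Mb. Means over 5 bins also gave correlations of 0.232 and -0.00392. The correlation at 2.1 to 5 Mb was 0.178 without the 12 cells with most bins at 0, 0.183 in odd-numbered and 0.162 in even-numbered cells, 0.212 without removal of the contact share, 0.201 for bins at 40 to under 60% and 0.161 without the 8 cells. Between chromosomes the correlation was 0.0484 without that removal, -0.000537 for bins at 40 to under 60%, -0.00368 on autosomes and -0.00447 in cells 96 to 124. The Spearman correlation of signal and frequency across bins was 0.769 in odd-numbered and 0.775 in even-numbered cells, 0.768 with signal from odd- and frequency from even-numbered cells, 0.775 the other way round, 0.817 in cells 1 to 94 and 0.626 in cells 96 to 124, where ends had 14.3%. The median over bins of chromosome 19 was 0. Except for these longer runs, the cause was not tested. An equal contact share in every cell, which 11 cells could not reach for lack of bins above 0, moved only the share of contact bins in runs of at least 1 Mb, from 54.3 to 52.6%. That share was far less stable elsewhere, with 67.2 and 19.8% at contact values of 0.5 and 2, 36.8% with 50000 reads, 76.4% with gaps bridged and 93.6% over 5 bins. The alternatives for gene lists, gene density and GC content were not run. Depth limits single contacts most in the 14 cells where a value of 1 stands for under 3 reads.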

Other observations

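The tests of missing chromosomes, of background and of thinned reads were chosen after the data were seen, that of thinned reads before its own result was known. On average, contact frequency stayed high next to frequent stretches of at least 1 Mb. The mean frequency was 66.4% in the first bin outside them, 50.7% at 1 Mb and 53.3% at 2 Mb, and 32.9% of bins at 1 Mb were under 20%. Besides chromosomes 5 and 12, the longest runs recurred on the long arm of chromosome 14 between 81.9 and 89.5 Mb, in 11 cells, and on chromosome 11 between 20.5 and 29 Mb, in 9 cells. Some cells had unusually much signal on 1 chromosome, relative to the rest of the cell and to the other cells, with over 2 times the median in 14 of 2124 pairs of cell and chromosome on 18 chromosomes. In cell 7 it was 2.92 times the median on chromosome 12, in cell 73 it was 2.87 times on chromosome 2 and 2.45 times on chromosome 21, and in cell 66 it was 2.76 times on chromosome 13. Cells 73 and 66 are shallow, with 35034 and 46574 reads. Over 4 parts of the frequent bins of chromosome 2 in cell 73 the excess ranged from 1.17 to 8.22 times. There 32.7% of the bins of that chromosome were in contact, against a mean of 34.9% over cells. On chromosome 13 in cell 66 the excess ranged from 1.68 to 6.43 times, with 42.5% of bins in contact against a mean of 38.9%. On chromosome 21 in cell 73, 22.5% of bins were in contact against a mean of 25.8%, and the only frequent bin had 0.781 times.

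In 10 pairs of cell and chromosome, a chromosome had under 5% of its usual signal. The share was lowest in cell 77, with 11 of its 148729 reads on 9:22 and 10 on chromosome 13. Cell 119 had 213 of 135954 reads on chromosome 5 and 65 on chromosome 15. Both cells had more background reads expected on these chromosomes than the other pairs. A chromosome that is present but away from the lamina would keep the background reads of its rarely contacted bins, yet cell 77 had 0 of 1316 expected on both sequences (upper counting limit 0.00280 of the expected level) and cell 119 had 14 of 1187 (upper limit 0.0198). The lowest other cells with at least 100 expected reads had 0.211 and 0.649. Pairs were picked by low signal over all bins, rarely contacted ones included, which favoured low counts. In both cells, a chromosome with its expected background reads would have had too much signal to be picked. This choice nearly fixed values under 0.211 and 0.649, so no conclusion is drawn from these comparisons. The counts show only that the rarely contacted bins of these chromosomes were nearly without reads too. Loss of the chromosome's DNA, in the cell or during handling, remains an untested candidate explanation, with biological and technical loss not separated. In the other 6 pairs, on chromosomes 11, 15, 20 and 21, only 2.57 to 82.0 background reads were expected and the upper limits reached 1.44; although cells 58 and 83 had limits of 0.245 and 0.176, below the 0.396 and 0.388 of the lowest cells with at least 100 expected reads, 3 of 109 and 1 of 43 other cells with at least as many expected reads as they had lay at or under those limits, so that presence away from the lamina and absence cannot be told apart in these pairs. Without the 8 cells concerned, the mean correlation between the arms of a chromosome was 0.321 ± 0.157 (SD over 17 chromosomes). The contact share of the cell was removed here too. The 13 cells with over 2 times the signal on a chromosome were kept. Their part in the correlations within chromosomes was not tested.

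The background in rarely contacted bins was 5.31 times higher, as a ratio of medians, in cells 96 to 124 than in cells 1 to 94. Depth was not the cause by itself, since 28 pairs of cells matched on reads had a median ratio of 4.45 and a ratio over 1 in 28 of 28, and the 25 pairs within 10% of each other in reads, without 3 that were farther apart, had 4.41. Additional reads spread evenly over the genome do not account for all of it either. Scaled to the bins without contact in odd-numbered cells of the first set, they predicted a ratio of 0.420 in bins at 5 to 20%, and 0.669 was observed, an excess of 0.249 ± 0.0886 (SD) that was above 0 in 28 of 28 cells. A step between library batches remains open. Background and sample number had a rho of -0.0289 within the first set and 0.0597 within the second, but the boundary was placed on the same values, so this adds no evidence, the labels name no batch, and no biological explanation was tested.

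The contact share rose with the reads of the cell, and the number of reads alone may not be the reason. In 109 cells thinned to 50000 reads, the contact share still had r = 0.720 with the reads before thinning, against 0.772 in the same cells before, and it was 0.793 in cells 1 to 94 and 0.650 in cells 96 to 124. The SD of the contact share fell from 4.52 to 3.48 percentage points. At a contact value of at least 2, without thinning, r over all 118 cells was 0.135, so the relation depends on the contact value. Whether cells with few reads also held fewer distinct DNA fragments was not tested, as the table carries no molecular identifiers, and no biological explanation was tested.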
